A study of Mus musculus with 7 samples.

How the data were processed

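Cerebellar RNA from 7 C57BL/6 mice was measured by RNA sequencing. The labels put 4 animals in a Cic knockout group, with En1-Cre and both Cic alleles floxed, and 3 in a control group titled wild type whose genotype field reads 1 floxed and 1 wild-type Cic allele with no Cre named. Cre driven by En1, a gene of the embryonic midbrain and hindbrain, removes floxed DNA in the cells that expressed it and their descendants. Per the labels' protocols, total RNA was turned into amplified double-stranded cDNA with a kit that primes from poly(A) tails and at random, and sheared cDNA was made into DNA libraries for an Illumina HiSeq. The labels give no age, sex or litter and do not say outright that each library is a separate animal; if any shared an animal, p-values would measure technical spread.

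The authors deposited raw counts per gene symbol, with 1 file per library and no normalization. Per the submitters' processing notes, STAR 2.5.3a, HTSeq and DESeq2 were used with build mm10. The versions of HTSeq and DESeq2, the gene annotation, the strand setting and any read filter are not given in the sources used here. Strand was therefore treated as unknown. Overlaps were not looked for over all genes, so a gene without a remark on overlap may still have one. Each file held 24421 gene symbols and 5 HTSeq summary rows, which stayed out of library sizes and tests. Of all entries, reads assigned to no feature made up 16.0% to 19.0%, ambiguous reads 1.27% to 1.37% and reads without a unique alignment 12.0% to 13.7%. Low-quality and unaligned reads were listed at 0. The files held 0 of the 13 mitochondrially encoded genes of a fixed list, so that list was not tested.

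Gene counts summed to between 102653765 and 121285349 per library, so 3 counts correspond to 0.0247 to 0.0292 CPM. Such floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Pairs of libraries within a group differed by 18.5 to 157 times the sampling variance over genes with at least 10 counts in the pair, and each library was counted as 1 replicate.

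Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr, which left 16905, and scaled by TMM in edgeR 4.0.16. Knockout and control were compared with the robust quasi-likelihood F test with genotype as the only term and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. All adjusted p-values for genes are from this edgeR test unless another tool is named. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values are TMM-scaled, and means carry the SD over libraries (n = 4 knockout, n = 3 control). Coordinates are those of GENCODE M21 on GRCm38, the assembly called mm10, and were found by symbol for 16718 of the tested genes.

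Before the data were examined, 23 gene lists (CIC targets, the CIC-ATXN1 complex, cerebellar and neighbouring cell types, and general programmes) were fixed from general knowledge, none on these samples. For each list the called members were counted over all genes tested and adjusted over the list alone. Of these lists, 21 had at least 2 tested members and were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. A list score is the mean log2 CPM of its members in a library. Scores were compared by two-sided exact permutation over the 35 splits into 4 and 3 libraries, where the smallest possible p is 0.0286.

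Named genes followed a rule fixed before the data were examined. It takes Cic first, then Atxn1, Atxn1l, En1 and En2. It then takes the 12 largest changes in each direction among called genes with a mean of at least 1 CPM and no overlap between groups, leaving out chromosome Y, Xist, unnamed gene models and pseudogenes. Last come all CIC targets and up to 4 members of every other list with the smallest adjusted p. Psmb8, B2m, Sqle, Calb1 and Ppp1r17, which passed in edgeR without knockout 3, and Grin2c and Kcnk9, which passed without control 2, but not with all libraries and genotype as the only term, were named after their values had been seen.

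Replicate numbers 1 to 3 occur in both groups. The deviations of same-numbered libraries from their group means correlated at 0.145, 0.288 and 0.713 across genes, all above the limit of 0.1 set for pairing. Libraries of different numbers passed it too, such as knockout 1 with control 2 (0.319) and knockout 4, which has no partner, with control 2 (0.297). The limit therefore cannot show pairing, and the main test leaves the numbers out. Only the libraries numbered 3 correlated best with each other, both of them high in choroid plexus transcripts. Knockout 2 correlated best with control 2, but knockout 1, control 1 and control 2 each correlated better with another library. A pairing would rest on the values alone and is uncertain. A fit with the number as a block, which leaves 2 residual degrees of freedom against 5, is given where it changed a call.

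The test was tried on simulated data with the means and library sizes of this comparison and 16787 genes tested. It called 43.9% of genes changed 1.5-fold, 71.4% of those changed 2-fold and 92.8% of those changed 4-fold, and 9 of its 148 calls (6.08%) were false. Each gene was drawn independently, without differences that many genes share, such as the choroid plexus transcripts in 2 libraries. These rates therefore need not hold for the real libraries. Alternatives covered size factors, library size only, filters, DESeq2 1.42.0, limma-voom, a fit that was not robust, the replicate block, each library left out, Xist as a covariate and 1 surrogate variable from sva 3.50.0. After the data had been seen, 3 more were added: a fit without knockout 3 and control 3, and fits with a choroid plexus score or the share of reads outside annotated genes as a covariate. That share is short for the reads that HTSeq assigned to no feature, out of all entries. The gene annotation and strand setting are not given, so it can include reads that lie within genes. Plots were drawn with matplotlib 3.10.9.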

Results

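Gene expression in whole cerebellum was compared between 4 mice with Cic deleted in the En1 lineage and 3 control mice with 1 floxed Cic allele. Cic encodes a transcriptional repressor that binds ATXN1, the protein altered in spinocerebellar ataxia type 1, and the series title concerns gain of function of this complex. The comparison asks which cerebellar transcripts change when Cic is lost. The labels name En1-Cre for the knockout group only, so an effect of Cre itself cannot be told apart from loss of Cic. The files gave 102653765 to 121285349 gene counts per library.

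Cic itself was lower in every knockout library. Its whole-gene level was 144 to 147 CPM in the 4 knockouts and 216 to 257 CPM in the 3 controls (means 146 ± 1.33 and 232 ± 22.2 CPM, SD), a log2 fold change of -0.66 (SE 0.0622, adjusted p = 0.00256). Cic lies on chromosome 7 at 25267704 to 25294159. Counts over the whole gene include exons outside the floxed part and cells outside the En1 lineage, and the controls carry a floxed allele, so the remaining level does not measure how much of the gene was deleted. Its binding partner Atxn1 was at 80.8 ± 4.47 CPM in the knockouts and 67.3 ± 4.60 CPM in the controls (log2 fold change 0.26, SE 0.0621), which was not called (adjusted p = 0.0767) but passed with the replicate block (adjusted p = 0.0454), library size only (0.0496), DESeq2 (0.00504), 1 surrogate variable (0.0355) and the choroid plexus score as a covariate (0.0496). Leaving out control 2 (adjusted p = 0.0405) or knockout 3 (0.0366) also brought it past the threshold, within a range of adjusted p from 0.00504 to 0.57 over all alternatives. Atxn1l, the paralog of Atxn1, did not differ detectably (log2 fold change 0.15, SE 0.0681, adjusted p = 0.338), nor did En1 (0.14, SE 0.238, adjusted p = 0.815) or En2 (0.10, SE 0.0394, adjusted p = 0.27). Of the 8 members of the CIC-ATXN1 complex list, Cic was the only one called in edgeR with all libraries, TMM and genotype as the only term. The list as a whole was not called (camera adjusted p = 0.829).

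Known CIC target genes were higher in the knockout as a list. Of the 18 listed targets 9 were called higher in the knockout and 0 lower, or 13 higher and 1 lower (Dusp5) when adjusted over the list alone. Etv4, an ETS transcription factor, rose 8.61-fold, from 16.5 ± 1.79 to 142 ± 11.9 CPM (log2 fold change 3.11, SE 0.0976, adjusted p = 8.01e-06). Its relative Etv5 rose 4.17-fold to 379 ± 18.3 CPM (adjusted p = 0.000458), Maff, a small MAF transcription factor, 4.43-fold (adjusted p = 0.000932) and Shc3, a neuronal signalling adaptor, 3.89-fold (adjusted p = 0.00021). All 4 knockout libraries lay above all 3 controls for each called target.

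The remaining called targets included negative regulators of receptor tyrosine kinase and ERK signalling. The ERK-pathway phosphatases Dusp4 and Dusp6 rose by log2 fold changes of 1.69 (SE 0.157) and 1.05 (SE 0.0797), and the inhibitors Spry4 and Spred3 by 1.31 (SE 0.0949) and 1.03 (SE 0.0628). Ptpn9, a tyrosine phosphatase, rose by 0.51 (SE 0.0476, adjusted p = 0.00256). Relatives of these genes were not called in edgeR with genotype as the only term: log2 fold changes were 0.20 for Spry1, -0.02 for Spry2, 0.17 for Spred2 and 0.33 for Spred1 (adjusted p = 0.365, 0.905, 0.547 and 0.0617). The sign of Spry2 turned without knockout 3 or control 3. Etv1 (0.24, adjusted p = 0.0618), Fosl1 (0.87, at 0.215 ± 0.0572 against 0.118 ± 0.0491 CPM) and Dusp5 (-0.28, adjusted p = 0.106) were also not called. Cyclin D1 (Ccnd1) had a log2 fold change of 1.19 (SE 0.254, adjusted p = 0.0738), and the clock gene Per2 had 0.65 (adjusted p = 0.0993, or 0.00204 with the replicate block). Without knockout 3, Spred1 (adjusted p = 0.0437), Etv1 (0.0262) and Ccnd1 (9.09e-05) passed, as did Spred1 without control 3 (0.0362) and Etv1 without control 2 (0.0452). DESeq2 called Spred1 (adjusted p = 0.00108), Etv1 (2.44e-05), Ccnd1 (0.00103) and Per2 (0.00046) higher and Dusp5 (0.0159) lower. These genes other than Dusp5 also passed with 1 surrogate variable (0.0239, 0.0217, 0.00491 and 0.0184) and with the choroid plexus score as a covariate (0.0279, 0.0284, 0.0107 and 0.0153). Without both knockout 3 and control 3 Spred1 (0.0143) and Ccnd1 (0.000402) passed, and Etv1 did with library size only (0.0391) or a filter on CPM (0.0388). No single omitted library ended the call of any of the 9 targets, but Dusp4 was not called with the share of reads outside annotated genes as a covariate (adjusted p = 0.0691). The list stood above all other genes by camera (adjusted p = 1.85e-17; adjusted p = 0.0368 with an estimated correlation), with a median log2 fold change of 0.95, and fry gave an adjusted p of 3.87e-05.

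**Figure D1:**
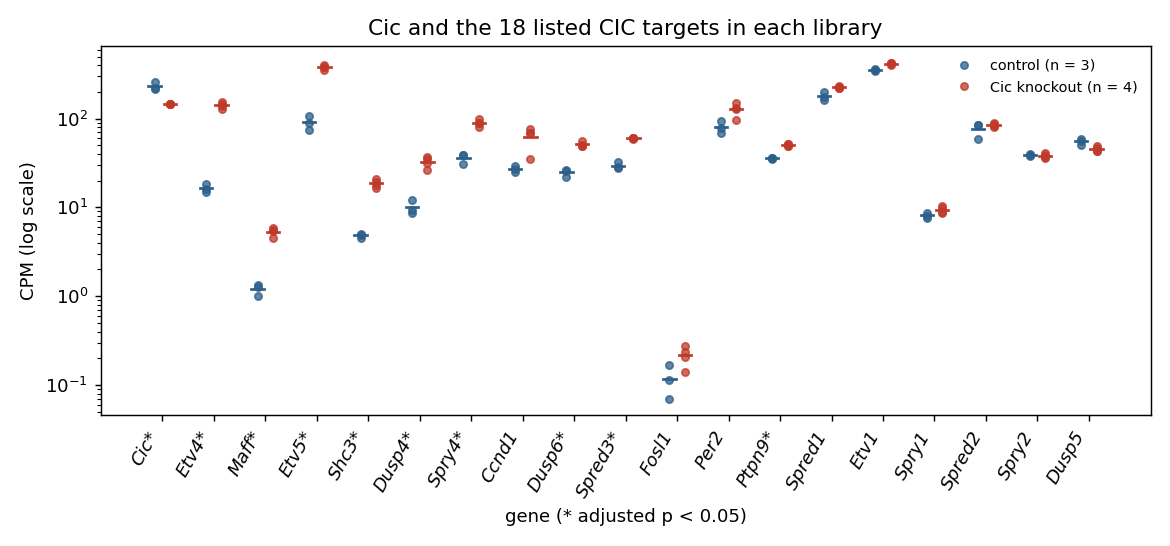
CPM on a log scale of Cic and the 18 listed CIC targets, ordered by fold change, in each library. Points are libraries (blue, 3 controls; red, 4 knockouts), short lines are group means and asterisks mark adjusted p below 0.05; the knockout points of Etv4 centre on 142 CPM and the control points on 16.5 CPM.

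Across the 16905 genes tested, 212 were higher and 140 lower in the knockout, and 2741 had an unadjusted p below 0.05. Higher genes moved further: their median log2 fold change was 0.70 against -0.45 for the lower ones, and 71 rose but only 21 fell by more than 2-fold. All 352 called genes had no overlap between the groups, as did 15.4% of all genes against 5.71% by chance. Counts depended on the libraries included. Without knockout 1, 2, 3 or 4 they were 65, 99, 493 and 79 higher and 21, 57, 349 and 28 lower, and without control 1, 2 or 3 they were 77, 371 and 78 higher and 25, 205 and 24 lower. DESeq2 called 675 and 497, while the share of reads outside annotated genes as a covariate left 46 higher and 12 lower, 52 of them among the 352. That share was 18.6 ± 0.365% in the knockouts and 17.0 ± 1.38% in the controls (exact permutation p = 0.0857), with control 2 at 18.6%. Apart from control 2 it follows the groups, so a call lost with it can reflect lost precision and does not show that the share explains the change. All 352 genes kept their direction with it.

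Genes outside the CIC target list also rose. Oxtr, the oxytocin receptor, rose 5.63-fold, from 1.52 ± 0.147 to 8.53 ± 2.43 CPM (adjusted p = 0.00323), and Tph2, the neuronal tryptophan hydroxylase of serotonin synthesis, 4.79-fold, from 0.846 ± 0.191 to 4.05 ± 1.44 CPM (adjusted p = 0.0227). Colq, the collagen tail of acetylcholinesterase, rose 3.95-fold to 32.9 ± 2.67 CPM (adjusted p = 0.0286). Afp, which encodes alpha-fetoprotein, rose 5.76-fold to 2.10 ± 0.820 CPM (adjusted p = 0.0213), Clca4a 4.88-fold (adjusted p = 0.0101) and the axonemal dynein gene Dnah8 3.97-fold (adjusted p = 0.00142). Necab3 (4.48-fold, 93.3 ± 23.9 CPM) and Actl10 (6.00-fold, 3.62 ± 0.912 CPM) overlap on chromosome 2, at 154544399 to 154558890 and 154551776 to 154553276 on opposite strands, so their separate levels are uncertain. With the replicate block Tph2 (adjusted p = 0.081) and Colq (adjusted p = 0.0556) were no longer called. Omitting a single library ended the calls of Tph2 in 6 cases (adjusted p = 0.11 without control 1, its highest), Afp in 5 (0.101 without control 1), Colq in 4 (0.131 without control 1) and Necab3 in 2 (0.0765 without control 3). With the share of reads outside annotated genes as a covariate, Dnah8 (adjusted p = 0.0343) and Colq (0.044) were called, and Oxtr (0.0522), Actl10 (0.0643), Necab3 (0.0863), Clca4a (0.211), Tph2 (0.23) and Afp (0.248) were not. With Xist as a covariate Tph2 (0.0528), Necab3 (0.0514), Afp (0.0662) and Colq (0.0922) were not called, nor were Tph2 (0.059) and Afp (0.0603) in limma-voom.

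Among the 12 largest decreases at a mean of at least 1 CPM, Ostn, which encodes osteocrin, fell from 4.93 ± 0.211 to 0.992 ± 0.515 CPM (log2 fold change -2.31, SE 0.377, adjusted p = 0.0267), the growth factor gene Bmp5 fell by 1.23 on the log2 scale (SE 0.218, adjusted p = 0.0341) and Sost, the gene of sclerostin, from 3.24 ± 0.810 to 1.29 ± 0.373 CPM (adjusted p = 0.0372). Hapln2, a hyaluronan link protein of nodes of Ranvier, fell by 1.19 on the log2 scale (SE 0.165, adjusted p = 0.0165), and Sdc1, the proteoglycan syndecan-1, by 1.06 (SE 0.103, adjusted p = 0.00263). Tunar, Fam163b and Prr16 fell by 1.26, 1.37 and 1.10 (adjusted p = 0.00694, 0.00826 and 0.00746). Ccdc3 (-1.71, adjusted p = 0.0483), Slc4a1 (-1.62, adjusted p = 0.00946), Serpina3n (-1.39, adjusted p = 0.0237) and Fbxw15 (-1.36, adjusted p = 0.00617) were also lower, and Serpina3n and Fbxw15 belong to families of similar genes that can share reads. Omitting a single library ended the calls of Ostn in 5 cases (adjusted p = 0.103 without control 1, its highest), Ccdc3 and Sost in 5 each (both 0.157 without control 1), Bmp5 in 4 (0.106 without knockout 4), Serpina3n in 3 (0.0807 without control 3), Hapln2 in 2 (0.0689 without knockout 1) and Slc4a1 in 1 (0.053 without control 1). Ccdc3 was also not called with library size only (adjusted p = 0.0529) or with no filter on low counts (0.0624). With Xist as a covariate Ccdc3 (0.157), Bmp5 (0.12) and Sost (0.11) were not called, nor was Serpina3n without both knockout 3 and control 3 (0.0516). Of the 12 decreases, only Sdc1 (adjusted p = 0.0433) and Fam163b (0.0295) were called with the share of reads outside annotated genes as a covariate.

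Astrocyte and Bergmann glia markers were lower as a list. Of 16 members 4 were called lower, or 6 when adjusted over the list alone, and 0 were called higher. Log2 fold changes were negative for 14 members and positive for 2. Gdf10, a marker of Bergmann glia, fell from 232 ± 14.8 to 155 ± 5.77 CPM (log2 fold change -0.59, SE 0.0555, adjusted p = 0.00256) and Agt, which encodes angiotensinogen, from 92.2 ± 5.99 to 56.8 ± 5.90 CPM (-0.70, SE 0.0838, adjusted p = 0.00694). Ndrg2 (-0.40, adjusted p = 0.019) and the water channel gene Aqp4 (-0.42, adjusted p = 0.0408) were lower too. The list's median log2 fold change was -0.18 (camera adjusted p = 1.79e-06; adjusted p = 0.195 with an estimated correlation), and fry gave an adjusted p of 0.00592, or 0.198 with the replicate block. No single omitted library ended the calls of Gdf10 and Agt, whereas 5 each ended those of Ndrg2 (highest adjusted p = 0.101, without control 1) and Aqp4 (0.164, without control 3). With the share of reads outside annotated genes as a covariate, Gdf10 was called (adjusted p = 0.0323) and Agt (0.122), Ndrg2 (0.217) and Aqp4 (0.166) were not. Xist as a covariate also ended the calls of Ndrg2 (0.0726) and Aqp4 (0.11), and leaving out both knockout 3 and control 3 that of Aqp4 (0.095).

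Myelin genes were slightly lower as a group by camera with the preset correlation, but not by fry (adjusted p = 0.379). Their list scores overlapped between groups (exact permutation p = 0.143). All 16 oligodendrocyte markers had negative log2 fold changes, with a median of -0.31 (camera adjusted p = 6.76e-05; adjusted p = 0.827 with an estimated correlation), and Cldn11, a tight junction gene of myelin, was the only one called (-0.83, SE 0.124, adjusted p = 0.0213), a call lost under 4 single omissions (up to 0.0929 without control 3), with Xist (0.0569) or the share of reads outside annotated genes (0.198) as a covariate, and without both knockout 3 and control 3 (0.0731). Mal had -0.36 (adjusted p = 0.203, or 0.0463 with the replicate block). Among 16 oligodendrocyte precursor markers Olig1, a transcription factor of this lineage, was lower (-0.39, SE 0.076, adjusted p = 0.0412; lost under 5 single omissions, up to 0.159 without control 3, without both knockout 3 and control 3, at 0.114, and with that share, at 0.328). This list was not called (camera adjusted p = 0.173, or 0.0107 without knockout 2). Bcas1 there had -0.56 (adjusted p = 0.151, or 0.00927 with the replicate block and 0.0289 without knockout 2). Cholesterol synthesis genes had a median of -0.13 (camera adjusted p = 0.0154; adjusted p = 0.827 with an estimated correlation and 0.0931 with the replicate block), and the list was not called without knockout 4 (0.116) or control 1 (0.0642), or with the share of reads outside annotated genes as a covariate (0.101). For this list fry gave an adjusted p of 0.475 and the exact permutation of scores a p of 0.143. In edgeR 0 of its 16 members were called, with 6 lower at an unadjusted p below 0.05 and 0 called by DESeq2 or limma-voom. Without knockout 3, 3 were lower: Hmgcs1, Sqle and Msmo1 (adjusted p = 0.0383, 0.0473 and 0.0461).

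Interferon response genes were higher in the knockouts as a list by camera with the preset correlation. No member passed alone in edgeR with all libraries and genotype as the only term. All 14 had positive log2 fold changes, with a median of 1.00 (camera adjusted p = 8.61e-09; adjusted p = 0.576 with an estimated correlation), and fry gave an adjusted p of 0.104. In edgeR 0 were called over all genes and 12 were higher when adjusted over the list alone. At an unadjusted p below 0.05, 13 were higher, and DESeq2 called 10 and limma-voom 0. The estimated correlation of the members was 0.606, so these counts are not separate results. Without knockout 3, edgeR called 4: Irf7, Usp18, Psmb8 and B2m (adjusted p = 0.025, 0.0366, 0.0325 and 0.0184); without knockout 2 it called Usp18 (0.0386). Irf7, a transcription factor of this response, had a log2 fold change of 1.75 (SE 0.361, adjusted p = 0.0628). Usp18 averaged 7.50 ± 3.49 CPM in the knockouts and 2.20 ± 0.258 CPM in the controls (adjusted p = 0.064), and Oasl2 22.5 ± 9.82 and 6.54 ± 1.49 CPM (adjusted p = 0.0767). With the replicate block these passed (adjusted p = 0.0115, 0.0454 and 0.00927). The list score was 4.48, 3.58, 3.73 and 4.35 in knockouts 1 to 4 and 2.99 to 3.12 in the controls (exact permutation p = 0.0571, or 0.3 adjusted over the 21 lists, n = 4 and 3). Cxcl10, an interferon-induced chemokine placed in the astrogliosis list, rose 2.49-fold to 3.39 ± 0.456 CPM (adjusted p = 0.0224; lost under 4 single omissions, up to 0.101 without control 1, and with Xist, at 0.0647, or the share of reads outside annotated genes, at 0.248, as a covariate), while Serpina3n of that list fell, and the 12 astrogliosis genes were not called together (camera adjusted p = 0.829).

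Ribosomal protein genes were slightly lower as a list by camera with the preset correlation. No member was called alone in edgeR with all libraries and genotype as the only term. The 18 members had a median log2 fold change of -0.20 (quartiles -0.22 and -0.17; camera adjusted p = 8.61e-09; adjusted p = 0.827 with an estimated correlation). Fry gave an adjusted p of 0.155 and the exact permutation of list scores a p of 0.0571. In edgeR 0 were called over all genes and 18 were lower when adjusted over the list alone. All 18 had an unadjusted p below 0.05, DESeq2 called 5 and limma-voom 0. The members moved together (estimated correlation 0.948), so these counts are not separate results. Without control 2 edgeR called 11, and without knockout 3 it called 1, Rps6 (adjusted p = 0.0473). The list score of control 2 was 7.61, beside 7.48 to 7.61 in the knockouts and 7.82 in both other controls, the same division as in the share of reads outside annotated genes (18.6% in control 2, 18.2% to 19.0% in the knockouts, 16.0% and 16.5% in the other controls).

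Purkinje signalling genes were slightly higher as a list by camera with the preset correlation. Fry did not call them (adjusted p = 0.475), and the exact permutation of list scores gave a p of 0.257. All 18 Purkinje signalling genes had positive log2 fold changes, with a median of 0.18 (camera adjusted p = 0.0029; adjusted p = 0.827 with an estimated correlation, and 0.362 with the share of reads outside annotated genes as a covariate). Of these Cacna1g, a T-type calcium channel gene, was called (0.35, SE 0.0625, adjusted p = 0.0317; lost under 5 single omissions, up to 0.142 without control 3, and with Xist, at 0.106, or that share, at 0.275, as a covariate). The list score of control 2 was 8.13, within the knockout range of 7.88 to 8.28, and the other controls were at 7.86 and 7.85. The 16 Purkinje cell markers were not called as a list (median 0.19, camera adjusted p = 0.0545), and 0 passed in edgeR against 1 at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma-voom. Without knockout 3 that list was called (median 0.30, camera adjusted p = 1.48e-06; 0.0475 with the choroid plexus score as a covariate) and 4 members were higher: Calb1, Ppp1r17, Slc9a3 and Rgs8 (adjusted p = 0.0473, 0.0193, 0.0477 and 0.0325). Lhx1 passed with the replicate block (adjusted p = 0.0443), as did Barhl2 among the granule neuron markers (-0.37 and 0.0457 without knockout 3, 0.0458 with the block). Of the granule neuron markers Grin2c (0.37, adjusted p = 0.0373) and Kcnk9 (0.84, 0.0305) were higher without control 2. Granule neuron, inhibitory interneuron and unipolar brush cell markers were not called as lists (camera adjusted p = 0.596, 0.689 and 0.122), except the last without knockout 3 (0.00259). Among the interneuron markers Gad2, a GABA-synthesis enzyme, was lower (-0.25, SE 0.0462, adjusted p = 0.0369), but not with the replicate block (0.0778) or under 5 single omissions (up to 0.153 without control 3), with Xist (0.117) or the share of reads outside annotated genes (0.248) as a covariate, or without both knockout 3 and control 3 (0.0976).

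**Figure D2:**
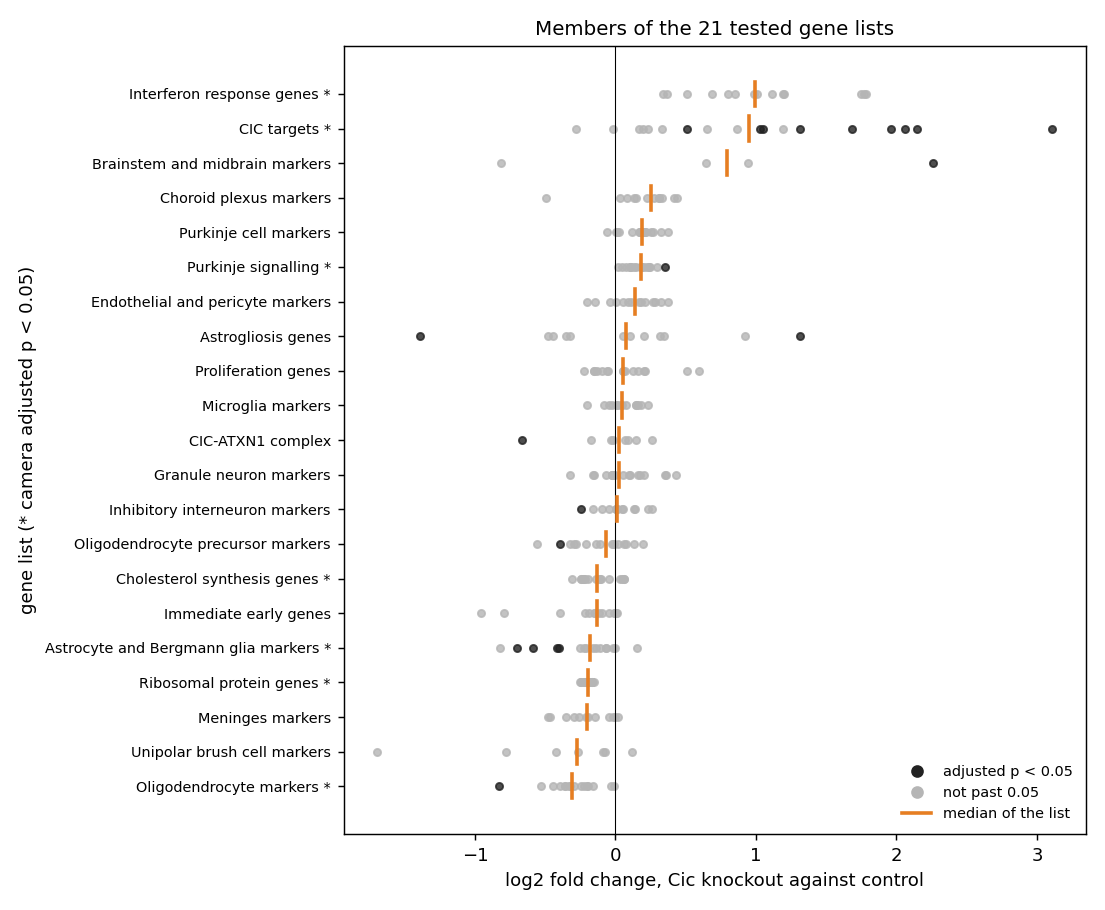
Log2 fold changes of the members of the 21 tested lists, knockout against control, on the horizontal axis, with lists ordered by median (orange lines). Black points passed an adjusted p of 0.05 and grey points did not; an asterisk marks a camera adjusted p below 0.05 with the preset correlation, as for the CIC targets (median 0.95) and the oligodendrocyte markers (median -0.31).

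Microglia, endothelial and pericyte, meninges, immediate early and proliferation lists were not called with all libraries and genotype as the only term (camera adjusted p = 0.689, 0.101, 0.463, 0.346 and 0.966). Single omissions brought 4 of these past the threshold: microglia higher without knockout 3 (0.00617), endothelial and pericyte higher without control 1 (0.00139) or knockout 2 (0.0101), meninges lower without control 2 (0.00219), and immediate early lower without knockout 2 (0.0428) or control 3 (0.00853). With the share of reads outside annotated genes as a covariate, endothelial and pericyte (0.00188) and meninges (0.0148) were higher, and with the choroid plexus score immediate early was lower (0.0186). Without both knockout 3 and control 3, microglia (0.0203), Purkinje cell (1.23e-05) and unipolar brush cell markers (0.0035) passed, the last of them lower. Egr4, an immediate early gene, had a log2 fold change of -0.96 (adjusted p = 0.0798, or 0.00919 with the replicate block), and the vascular transporter gene Slco1a4 had 0.37 (0.157, or 0.049 with the block and 0.0355 without knockout 2). Of the blood markers only Alas2 was tested (-0.08, adjusted p = 0.903). The brainstem and midbrain list had 4 tested members, of which Tph2 was called, with Slc6a4, the serotonin transporter, at 0.108 ± 0.0603 against 0.0553 ± 0.0433 CPM (list camera adjusted p = 0.393).

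Choroid plexus transcripts marked 1 library of each group. Ttr, the transthyretin gene abundant in that epithelium, reached 8006 CPM in knockout 3 and 5814 CPM in control 3 and lay at 13.9 to 112 CPM in the other libraries. Principal components were taken over the 2000 genes with the highest variance. The first (53.0% of the variance of those genes) separated knockout 3 and control 3 from the rest. The list did not differ between groups (median log2 fold change 0.25, but camera direction down, adjusted p = 0.689, or 0.009 without knockout 3), apart from Slc4a5 with the replicate block (adjusted p = 0.0107). Without both libraries 256 genes were higher and 146 lower, 233 of them among the 352. Xist, transcribed from the inactive X chromosome, was at 1556 and 1596 CPM in knockouts 1 and 2 and at most 14.7 CPM elsewhere, so it was high in no control. With Xist as a covariate 73 genes were higher and 31 lower, and all 352 called genes kept their direction. Because Xist was high in knockouts only, a call lost with it can reflect lost precision and does not show an effect of sex.

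**Figure D3:**
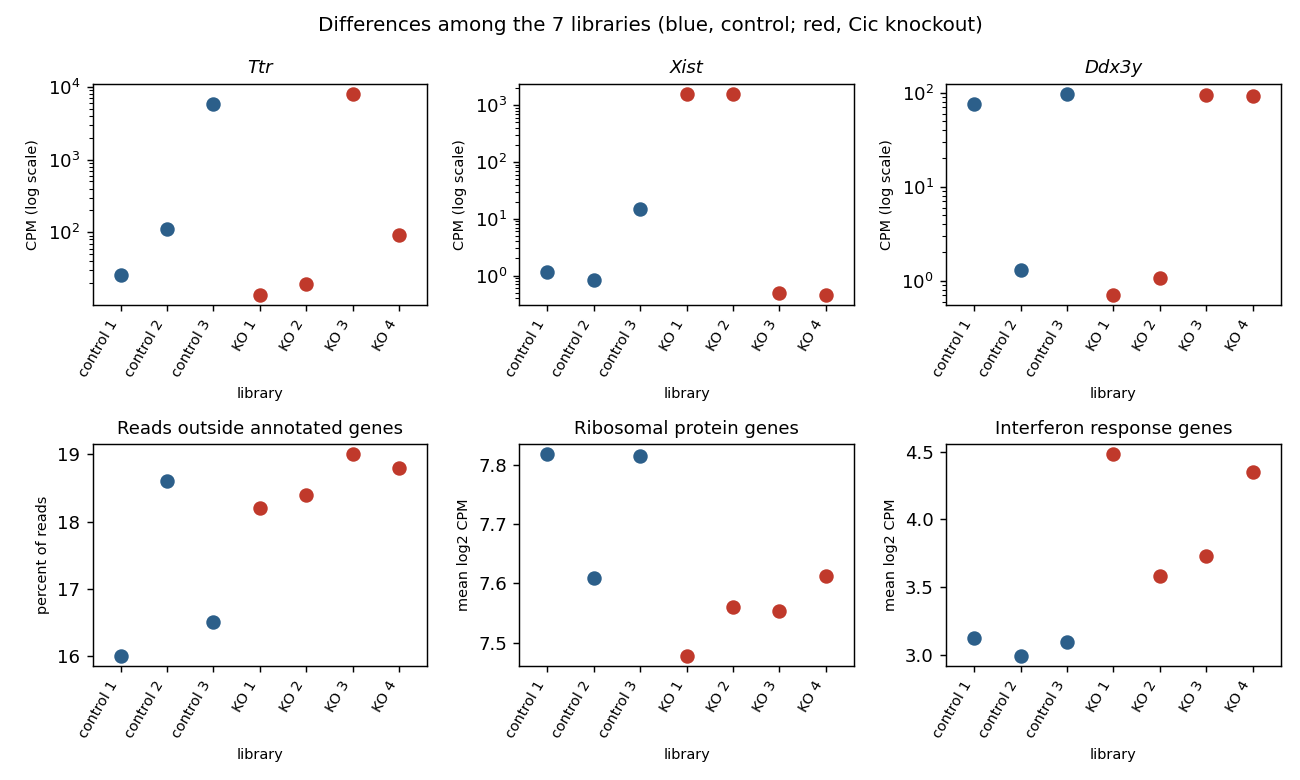
Ttr, Xist and Ddx3y in CPM (log scales), reads outside annotated genes (those assigned to no feature) in percent, and the ribosomal protein and interferon list scores in mean log2 CPM, for each library (blue, 3 controls; red, 4 knockouts; 1 point per library, no error bars). Ttr is high in control 3 and knockout 3 (5814 and 8006 CPM), control 2 is low for both Xist and Ddx3y (0.822 and 1.31 CPM), and every knockout lies above every control in the interferon score.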

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

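The splits of the libraries were planned, and the second interferon list was drawn up after the first had been seen but before its own values were; the other tests here were chosen after the results had been seen. A knockout library far from the other 3 was looked for in 142 values (119 named genes, the list scores and library measures), where chance marks about 1 in 20. Of these 15 stood out, 12 of them in knockout 3. The 12 include the choroid plexus score and members of its list, so the values are not independent and their excess over that rate cannot be judged. The groups of 3 controls were not tested.

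In knockout 3 the choroid plexus score was 6.20 (0.288 to 0.997 in the other knockouts), with Otx2 at 53.5 CPM, Slc4a5 at 61.4, Clic6 at 104 and Folr1 at 36.6 CPM, and the 10 most abundant genes took 3.31% of counts (2.74% to 2.80% in the others). All 12 choroid plexus markers were higher in knockout 3 and control 3 than in every other library, which is consistent with choroid plexus tissue in both dissected pieces. Loss of Cic as the source is argued against by the control library, whose score exceeded the knockout median by 4.87 log2 units. Whether both pieces were cut differently or on a shared day stays open.

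Among the knockouts, knockout 3 also stood apart for Sln (1.27 CPM), Samd3 (1.56 CPM), Dcn (46.5 CPM) and Hoxb3 (0.739 CPM), all higher than in the others. Controls 1 to 3 had 1.54, 0.925 and 1.66 CPM of Sln, 0.849, 0.495 and 1.55 of Samd3, and 59.6, 25.7 and 50.9 of Dcn. For these genes knockout 3 was thus near the controls. Sln was at 0.118 to 0.162 CPM in the other knockouts, and called lower without knockout 3 (log2 fold change -3.3, edgeR adjusted p = 0.00127). Knockout 3 was lower than the other knockouts for Tph2 (1.92 CPM against 4.57 to 5.07) and for the CIC target score (5.38 against 5.51 to 5.53, controls 4.43 to 4.54). Among the knockouts, Kit (369 CPM) and Cdh22 (89.1 CPM) were highest in knockout 1, and Slco1a4 (45.1 CPM) was lowest in knockout 2.

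The interferon response differed in size among the knockouts, and may extend beyond the 14 genes listed at first. A second list of 46 other interferon-stimulated genes had a median log2 fold change of 0.577 (31 higher when adjusted over the list alone, 0 called over all genes; camera p = 9.87e-16, 0.14 with an estimated correlation). More microglia are argued against by the median of 0.0445 for their markers (0.142 and called higher by camera without knockout 3, against 0.996 for the interferon list in all libraries), and sex by the knockouts, where the Xist-positive and Y-positive libraries interleaved and their mean scores differed by -0.006. Loss of Cic, the presence of Cre and an exposure of the knockout animals to an immune stimulus stay open, since the labels give nothing to part them.

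For the lower ribosomal protein genes, loss of Cic cannot be told apart from a library property that control 2 shares with the knockouts, because the lowest control and highest knockout scores touch (difference -0.002) and the share of reads outside annotated genes itself averaged higher in the knockouts. With that share as a covariate the list's median moved from -0.197 to -0.0764 (camera adjusted p = 0.0148), but the share was chosen because it divides the libraries as the score does, so the move decides nothing. Scaling stays open: library size alone gave -0.202, but with scaling factors of 0.984 to 1.02 that setting hardly moved any value.

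The counts of called genes were set against all 35 splits of the libraries into 4 and 3. The real split called 352 genes and 1 other called more (423), so 2 of 35 were as large and chance is not excluded for the total. That other split exchanged knockout 3 with control 2, which puts together knockout 3, control 1 and control 3, the only libraries with positive values on the first principal component (43.3, 3.06 and 39.5). It points to a structure of the samples besides genotype, and it parted 1 of the 3 numbered pairs. Among the 8 splits that part all 3 pairs, as the real one does, each of the other 7 called 0 genes. The median over all splits other than the real one was also 0, so this is not particular to them. The split of knockout 3 and the 3 controls against the other knockouts called 215. The fit with the replicate block called 310 genes higher and 204 lower.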

How the results depend on the processing

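The alternatives with the choroid plexus score, without knockout 3 and control 3, and with the share of reads outside annotated genes were chosen after the data had been seen. Cic stayed lower under every alternative (log2 fold change -0.80 to -0.58, highest adjusted p 0.0152), and all 352 called genes that were tested kept their direction, which is partly fixed by their groups not overlapping. The counts of higher and lower genes moved by over 1.5 times with DESeq2 (675 and 497), Xist as a covariate (73 and 31), 1 surrogate variable (486 and 405), the choroid plexus score (376 and 313) and the share of reads outside annotated genes (46 and 12). Omitting single libraries gave 65 (without knockout 1) to 493 (without knockout 3) higher and 21 to 349 lower, from the same libraries. The cause was not tested. With the replicate block 310 genes were higher and 204 lower, 292 of them among the 352; among named genes and lists it changed no call beyond those given. At an adjusted p below 0.01 and 0.1, 80 and 733 genes passed. Of 21 lists 7 passed; 1 did with an estimated correlation, 2 with fry, and 6 to 11 without single libraries (11 without knockout 3). With the share of reads outside annotated genes 2 of the 7 were lost and 2 others gained. Of 39 called named genes, 13 passed under every alternative, 21 without any single library, 25 were lost with the share of reads outside annotated genes and 13 with Xist as a covariate. Among genes not called, Spry2 (-0.02) turned to 0.032 without knockout 3 and control 3 and 0.0171 with that share, and ranged from -0.0497 to 0.00913 without single libraries; En1 (0.14) ranged from -0.0184 to 0.324 without single libraries. Depth was high, and over genes with at least 10 counts in a pair the spread within groups was on average 18.5 to 157 times the sampling variance. For genes with few counts, such as Slc6a4 and Fosl1, counting error adds to that spread, and its part was not assessed gene by gene.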

Other observations

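The comparisons of neighbouring and sex-linked genes here were chosen after their values had been seen, and no hypothesis was tested.

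Pafah1b3, which encodes a catalytic subunit of a platelet-activating factor acetylhydrolase and is the next gene to Cic (chromosome 7, 25295049 to 25297986, opposite strand), was 1.99-fold higher in the knockout, at 30.0 ± 1.83 against 15.1 ± 1.71 CPM (n = 4 and 3; log2 fold change 0.99, SE 0.0868, edgeR adjusted p = 0.00209). Of the 15 genes tested within 200 kb of Cic it was the only one called besides Cic. The other 13 had log2 fold changes of -0.215 to 0.349, and the strand setting of the counts is not given. The lowest, 9130221H12Rik, lies within Gsk3a and the highest, 4732471J01Rik, spans Lipe, each on the opposite strand, so both levels are uncertain.

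Control 2 had neither Xist (0.822 CPM) nor the Y-linked Ddx3y (1.31 CPM), where the 4 Y-positive libraries had 76.5 to 97.5 CPM of Ddx3y and knockouts 1 and 2, which had Xist, 0.709 and 1.07 CPM. X-linked genes that escape inactivation were in control 2 near the Y-positive libraries: Kdm6a at 67.8 CPM (66.2 ± 6.78 in those, 94.5 in the Xist-positive ones), Eif2s3x at 50.4 (49.1 ± 2.83 and 73.4), Ddx3x at 483 (451 ± 27.1 and 588) and Kdm5c at 131 (116 ± 7.36 and 163). Its Cic level (257 CPM) and CIC target score (4.54) were those of a control. Control 3 had 14.7 CPM of Xist beside 97.5 CPM of Ddx3y.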
